A study of Mus musculus with 11 samples.

How the data were processed

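RNA from mouse liver was extracted with TRIzol and made into Illumina TruSeq libraries, per the labels' protocols, which also name a small RNA kit for the indexing. The submitters' processing notes name FastQC and the mm10 build; the aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. The deposited gene table gives a raw count per gene and library and an RPKM value, per the file headers. The authors' RPKM values match a division by the listed coding length and by a library total that exceeds the sum of the gene counts, which came to between 64.16% and 72.63% of it; RPKM was used only for that check. A second deposited table gives a raw count per exon of each transcript, per the file headers. An exon shared by transcripts is listed once for each, and overlapping genes can count a read more than once. Genes of the mitochondrial chromosome were at 0 in every library.

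The gene table holds 43346 genes, of which 42462 matched GENCODE release M21 by identifier, and 99.88% of those overlapped their position there. Libraries were grouped by the response label, with replicate numbers in accession order that pair nothing. Depth ran from 17876515 to 49884800 gene counts per library, and intervals and floors cover counting error only, since no molecular identifiers are named. Within a group, every pair of libraries differed by more than sampling noise, by at least 5.26 times the median chi-square that counting alone gives, so none was treated as a repeat of another.

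Responder and non-responder libraries (6 and 4) were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, a robust quasi-likelihood fit and F test with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change was its size divided by the root of F. CPM values are TMM-scaled. Gene lists fixed in advance (46, with 44 of at least 5 measured members) were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Macrophage gene Emr1 is the file's symbol for Adgre1. Shares of exon reads of Ctnnb1 and Met, over 1 transcript each and exons with a mean of 10 or more counts, were compared by two-sided exact permutation tests in scipy 1.17.1. The untreated library was compared without a test, by its place in the range of the treated libraries and by percentiles among 10000 random lists drawn in 20 expression bins.

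Genes named in the text were chosen by a rule set before the data were examined: up to 12 higher and 12 lower with the largest change past the threshold at an average log2 CPM of 1 or more, leaving out symbols that start with Gm and a digit or end in Rik; a fixed set of tumour and immune genes; the 3 members with the smallest p of each list past the threshold, and the top member of another list where it passed; and the 5 genes farthest above and 5 farthest below the treated range in the untreated library. Some genes that the rule took are not reported here, and were left out of the tests for a library standing apart. The tests, the lists and the alternatives were also set then, except 2 covariates added later. Alternatives were other scalings (RLE, upper quartile, library size only), other filters, DESeq2 1.42.0, limma-voom with and without quality weights, 1 surrogate variable (sva 3.50.0), sums of exon counts, another threshold, glmTreat, the title number as a covariate, the untreated library as a group of its own in the model, and each library left out in turn. Covariates chosen after seeing the data were a log2 exon index, the mean of the log2 relative densities of Ctnnb1 exon 12 and Met exon 17, and a 3′ coverage index, the median over 2426 genes of the log2 read density of the later over the earlier exons.

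The steps were tested on simulated data. Counts were drawn for the 17610 genes of the responder against non-responder comparison, and 17317 of them passed the filter again and were tested. Among those, the edgeR step found 4 of 64 genes changed 1.5-fold, 33 of 67 changed 2-fold and 51 of 65 changed 4-fold. It called 3 of 17092 unchanged genes. Changed genes that the filter dropped are left out of these shares. The camera step called the shifted list and 0 of the unchanged lists among 44, with genes drawn independently. The exact permutation step was run on 200 simulated exons with counting noise only and without adjustment over exons. It called 2.5% of unchanged ones at p under 0.05 and found all whose counts were raised 2-fold. The real libraries varied by more than counting noise and the real test was adjusted over exons, so this share does not carry over to them. Of the named genes, 13 shared 10% or more of their exon bases with another gene of at least 10% of their count and are uncertain, among them Kif20a, Acaa1b, Ndufb5, Ccna2, Cyp2u1, Ly6k, Fzd5, Akr1b7, Raet1e, Raet1d, Slc51b and Cxcl11. Members of families of near-identical genes are uncertain too, since the counting could split their reads: Hamp, Hamp2, Mup13, Ces1e, Cyp2c39, Cyp2a4, Gsta2, Klrb1b, Klrb1c, Hbb-bt, Acot1, Serpina1e and Sult1d1.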

Results

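Livers of FVB/NJ mice that carried hepatocellular carcinoma driven by expression of MET, a receptor tyrosine kinase, and β-catenin, the transcriptional effector of Wnt signalling, were profiled by RNA sequencing. The libraries fell into 6 from mice labelled as responders to an antibody against PD-1, an inhibitory receptor of T cells, 4 from mice labelled as non-responders and 1 whose response label gives no treatment. The treatment label of that last library names the antibody, so it is called untreated here only after its response label. Gene counts summed to between 17876515 (replicate 4) and 40565708 in responders, to between 25542066 and 39941835 in non-responders, and to 49884800 in the untreated library. Nothing in the labels says whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries. The series holds the anti-PD-1 part of a study on whether targeting β-catenin alters the response to that antibody.

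In livers of responders, the medians of type I interferon, proliferation and fetal liver gene lists were lower, and that of a periportal hepatocyte list was higher, than in livers of non-responders. These 4 lists passed with a preset correlation between genes and not with an estimated one (adjusted p = 0.414 each), and 22 of 29, 7 of 38, 4 of 20 and 10 of 18 of their genes passed singly. Their medians were -2.07, -1.18, -1.79 and 1.36. With the log2 exon index as a covariate they were -0.928, -1.02, -0.653 and 0.390. With the number in the sample title as a covariate they were -2.27, -0.568, -0.711 and 0.943. All 4 lists still passed with either covariate at the preset correlation. Hamp (ENSMUSG00000050440, mm10 chromosome 7, 30942371 to 30944017), which encodes the iron hormone hepcidin, stood at 633 ± 142 CPM (counts scaled to library size; SD, n = 6) in responders and at 74.1 ± 43.1 (SD, n = 4) in non-responders, a log2 fold change of 3.09 ± 0.40 (SE, edgeR adjusted p = 0.0105). Usp18 (ENSMUSG00000030107, chromosome 6, 121245906 to 121270916), a negative regulator of interferon signalling, stood at 3.74 ± 1.71 CPM (SD, n = 6) against 34.1 ± 13.01 (SD, n = 4), a log2 fold change of -3.19 ± 0.34 (SE, edgeR adjusted p = 0.0105). Of 17610 genes tested, 723 were higher and 1025 lower in responders by edgeR's quasi-likelihood test. The groups did not overlap in 1283 of the 1748 called genes. Over all tested genes they did not overlap in 11.26%, where chance gives 0.9524%. The counts rest on single libraries: without non-responder replicate 2, 38 genes were higher and 41 lower, and without responder replicates 1, 2, 3 and 5 in turn 425, 324, 996 and 309 genes were called in all. Of the 101 called genes that the naming rule took, 85 missed the threshold without non-responder replicate 2. Among those same genes 64 missed it without responder replicate 5, 59 without replicate 2, 49 without replicate 1, 17 without replicate 3, 4 without replicate 6 and 3 without replicate 4. Without non-responder replicates 4, 1 and 3 in turn 12, 11 and 6 of them missed it. Reads of non-responder replicate 1 lay toward the 3′ ends of genes (a log2 coverage index of 1.19, against -0.20 to 0.07 in the other treated libraries), and without it 818 genes were higher and 894 lower. With the number in the sample title as a covariate 1 gene was called by edgeR (1857 at an unadjusted p under 0.05). The median log2 change of the 1748 genes, in its direction without the covariate, was then 0.846 against 1.009 and all kept their sign, while the median SE rose from 0.2307 to 0.3666. Responders carry the numbers 1, 3, 9, 13, 16 and 29 where non-responders carry 26, 30, 32 and 37.

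Among the largest decreases in responders were genes near the floor there. Cacna1h, a calcium channel gene, had 0.0487 ± 0.0430 CPM (SD, n = 6) in responders and 10.6 ± 16.5 (SD, n = 4) in non-responders, with a log2 fold change of -7.84 ± 1.20 (SE, edgeR adjusted p = 0.0149). A2m, a protease inhibitor, had a log2 fold change of -7.07 and A1bg one of -6.79. Stc1, Akr1b7, Ly6k, Wisp2, Tspan8, Cyp17a1 and Klrb1b followed, with log2 fold changes between -5.74 and -4.49. The SD of the non-responders exceeded their mean for Cacna1h, A2m, Ly6k, Cyp17a1 and Klrb1b. Among increases, Hamp2 had a log2 fold change of 3.01 and the major urinary protein gene Mup13 one of 3.52. Susd4, Raet1e, Raet1d, Chrm3, Ces1e, Ankrd55, Capn8, Igfbp2 and Slc22a7 lay between 2.98 and 2.33. Hamp with Hamp2, Raet1d with Raet1e and Mup13 have near-identical relatives, and Raet1d and Raet1e share 363 exon bases, so reads could be split between them. In edgeR fits that left out 1 library each, Ankrd55, Usp18, A1bg, Hamp, Hamp2, Cacna1h, Chrm3 and A2m stayed past the threshold in all 10 fits, with adjusted p of at most 0.0492. The other genes of this paragraph lost the threshold without non-responder replicate 2, with adjusted p up to 0.1125 for Mup13. Raet1e, Stc1, Ly6k, Wisp2 and Tspan8 lost it in that fit only. The rest lost it in further fits: Mup13 passed in 1 of the 10, Slc22a7 in 3, and Ces1e and Klrb1b in 5.

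**Figure D1:**
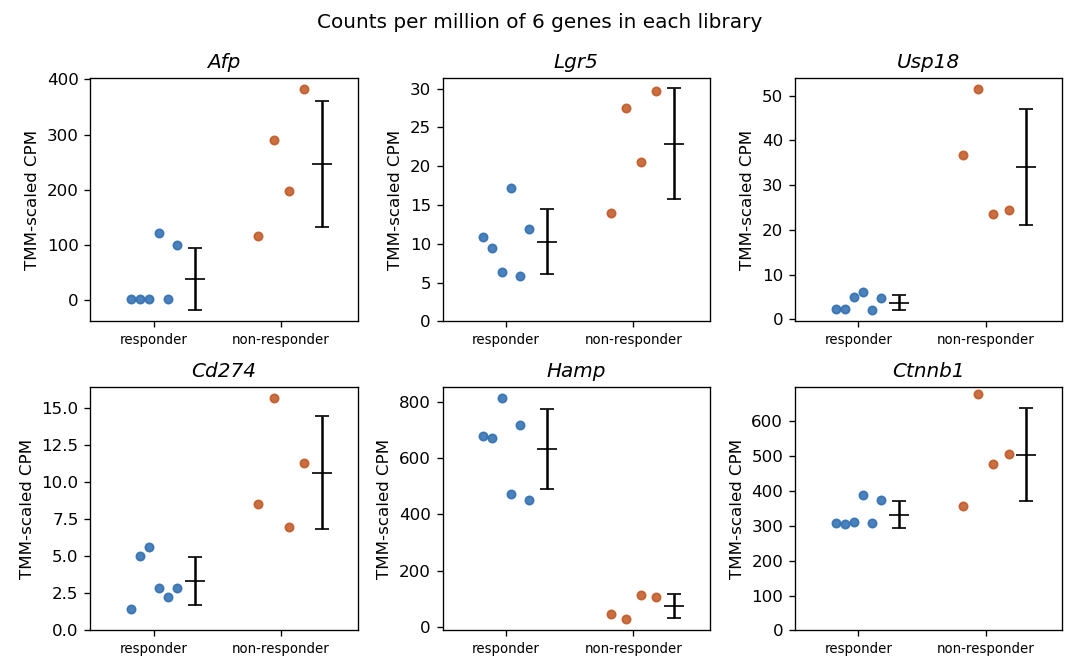
TMM-scaled CPM of 6 genes in each responder and non-responder library; points are libraries and the bar beside them is the mean with its SD. Hamp was between 450.6 and 811.1 in responders and at most 115.0 in non-responders, while Afp was at most 2.28 in responder replicates 1, 2, 3 and 5, and 121.8 and 100.02 in replicates 4 and 6.

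Lists of interferon response genes had lower medians in responders. Of 29 type I interferon response genes 22 were lower in responders and 7 did not pass (27 lower when adjusted over the list alone). Their median log2 fold change was -2.07 (camera adjusted p = 8.42e-13), and -0.928 with the log2 exon index as a covariate (camera adjusted p = 3.38e-05). The list's adjusted p = 0.414 with an estimated correlation. Oas1a, an antiviral enzyme, had a log2 fold change of -3.15 and Rtp4 one of -1.33. Of 38 measured interferon-gamma and antigen processing genes 11 were lower and 27 did not pass (21 lower adjusted over the list alone). Interferon-gamma genes had a median of -0.78 (camera adjusted p = 1.41e-09, adjusted p = 0.414 with an estimated correlation), and of -1.45 with the log2 exon index (camera adjusted p = 2.94e-12). Nlrc5, the activator of MHC class I genes, had a log2 fold change of -1.26, the guanylate binding protein gene Gbp2 one of -2.41 and Irgm1 one of -1.21. Without non-responder replicate 2, Usp18 and Nlrc5 kept the threshold (edgeR adjusted p = 0.0175 and 0.0492) while Oas1a, Rtp4, Gbp2 and Irgm1 did not (0.0557, 0.0603, 0.0743 and 0.0759).

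Several lists of immune genes had lower medians in responders. Cd274, which encodes the PD-1 ligand, stood at 3.34 ± 1.63 CPM (SD, n = 6) in responders and 10.6 ± 3.81 (SD, n = 4) in non-responders, a log2 fold change of -1.66 ± 0.35 (SE, edgeR adjusted p = 0.0213). Pdcd1, which encodes PD-1, had 0.0544 ± 0.0975 CPM in responders and 0.613 ± 0.230 in non-responders, a log2 fold change of -3.28 (edgeR adjusted p = 0.0248). It was near the floor, with 12 reads over all responders and 90 over all non-responders. Among responders it was highest in replicate 6 (0.249 CPM). Of 23 checkpoint and co-stimulation genes 5 were lower and 18 did not pass (6 lower adjusted over the list alone), Icosl among them at -2.15. Checkpoint and co-stimulation genes had a median of -0.52 (camera adjusted p = 0.00627, adjusted p = 0.414 with an estimated correlation). Of 19 chemokine genes 4 were lower and 1 higher (8 and 1 adjusted over the list alone). Chemokine genes had a median of -1.11 (camera adjusted p = 0.00356, adjusted p = 0.414 with an estimated correlation). Cxcl14 had -2.13 and Cxcl11 -1.60, while Cxcl12, made by stromal cells, rose from 212 ± 59.0 CPM (SD, n = 4) in non-responders to 425 ± 75.6 (SD, n = 6). Of 7 natural killer cell genes 3 were lower (4 adjusted over the list alone). Natural killer cell genes had a median of -1.12 (camera adjusted p = 0.0111, adjusted p = 0.414 with an estimated correlation). Of 27 T cell and cytotoxic genes 3 were lower (3 adjusted over the list alone). T cell and cytotoxic genes had a median of -0.40 (camera adjusted p = 0.0301, adjusted p = 0.584 with an estimated correlation). With the title number as a covariate the natural killer, T cell and dendritic lists did not pass (camera adjusted p = 0.116, 0.320 and 0.113). Gzmb (log2 fold change -1.40) and Prf1 (-1.69) were lower members of both lists, Klrb1c (-3.11) of the natural killer list and Ccl5 (-1.44) of the T cell list. The T cell list missed the threshold without responder replicate 1 and non-responder replicates 3 and 4 (camera adjusted p up to 0.343). The pan T cell gene Cd3e had -0.23 ± 0.42 (SE) and Cd8a -1.07 ± 0.56 (SE), and neither passed (edgeR adjusted p = 0.760 and 0.244). Ccl4, Cxcl9, H2-Ab1, S100a8 and the macrophage gene Emr1 did not pass either, with log2 fold changes of -1.35, -1.02, -0.07, 0.00 and 0.11, and Ctla4 (13 counts in responders, 42 in non-responders) and Ifng (11 and 8) were too scarce to test. Of 20 monocyte and neutrophil genes 2 were lower, Ltf (-2.37) and Hdc (-0.51), while Plac8 had -1.19 and did not pass (4 lower adjusted over the list alone). Ltf had only 16 reads over all responders and 65 over all non-responders. Monocyte and neutrophil genes had a median of -0.48 (camera adjusted p = 0.0337, adjusted p = 0.489 with an estimated correlation). That list missed the threshold without responder replicates 4 and 6 and non-responder replicates 1 and 3 (camera adjusted p up to 0.135), and with the 3′ coverage index as a covariate (0.0508). Of 18 dendritic cell genes 0 passed in edgeR's test or adjusted over the list alone (4 at an unadjusted p under 0.05; 0 by DESeq2, 0 by limma-voom and 1 with quality weights). Naaa, Zbtb46 and Bst2 had -0.59, 0.34 and -0.61. The dendritic median was -0.27 (camera adjusted p = 0.0367, adjusted p = 0.559 with an estimated correlation). It passed in 3 of 10 fits that left out a library, those without responder replicates 2 and 3 and non-responder replicate 4 (adjusted p up to 0.0898 in the others). With the 3′ coverage index as a covariate the dendritic list did not pass (camera adjusted p = 0.0508). Without non-responder replicate 2, Cd274, Pdcd1, Icosl, Cxcl14, Cxcl11, Cxcl12, Gzmb, Prf1, Klrb1c, Ccl5, Ltf and Hdc all missed the threshold, with adjusted p between 0.0640 and 0.1369. Of the 10 fits that left out a library, Hdc passed in 1, Gzmb in 2, and Ccl5 and Cxcl11 in 4. The others of these genes passed in 5 to 8.

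Fetal liver, proliferation and β-catenin target lists had lower medians in responders, with a minority of their genes past the threshold. Of 20 fetal liver and carcinoma genes 4 were lower (14 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -1.79 (camera adjusted p = 2.12e-08, adjusted p = 0.414 with an estimated correlation); Akr1b7 had -5.05, Bex1 -3.71 and Nqo1 -0.93. Afp, the fetal serum protein, had 38.2 ± 56.7 CPM (SD, n = 6) in responders and 247 ± 115 (SD, n = 4) in non-responders, and its log2 fold change of -2.69 ± 1.31 (SE) did not pass (edgeR adjusted p = 0.217). It stood at 1.39 to 2.28 CPM in responder replicates 1, 2, 3 and 5, at 121.8 and 100.02 in replicates 4 and 6, and at 116.7 or more in every non-responder. Of 38 proliferation genes 7 were lower and 31 did not pass (18 lower adjusted over the list alone), with Kif20a, Cdca3 and Ccna2 between -1.35 and -1.22; Mki67 had -1.13 ± 0.75 (SE) and did not pass (edgeR adjusted p = 0.365). Proliferation genes had a median of -1.18 (camera adjusted p = 4.80e-11, adjusted p = 0.414 with an estimated correlation). With the title number as a covariate the proliferation and fetal liver medians were -0.568 and -0.711 (camera adjusted p = 0.0137 and 0.00361). With the log2 exon index they were -1.02 and -0.653 (camera adjusted p = 8.80e-07 and 0.0266). Kif20a and Ccna2 overlap exons of a neighbour on the other strand. Of 29 β-catenin target and perivenous genes 6 were lower and 1 higher (11 and 1 adjusted over the list alone). Target and perivenous genes of that list had a median of -0.83 (camera adjusted p = 1.70e-04, adjusted p = 0.437 with an estimated correlation), and of -0.259 with the title number as a covariate, where the list did not pass (camera adjusted p = 0.116). The amino acid transporter gene Slc1a4 had -2.37, the vasopressin receptor gene Avpr1a -1.13 and the stem cell receptor gene Lgr5 -1.17 ± 0.30 (SE, edgeR adjusted p = 0.0346), while Cyp27a1 had 0.62. Glul and Axin2, standard targets of the pathway, had -0.84 ± 0.44 and -0.93 ± 0.40 (SE) and did not pass (edgeR adjusted p = 0.251 and 0.161). Without non-responder replicate 2, every gene called in this paragraph missed the threshold, with adjusted p from 0.0568 to 0.1084.

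Lists of stress, matrix and blood genes had lower medians in responders too. Of 19 immediate early genes 5 were lower (9 adjusted over the list alone), with Klf6, Btg2 and Jun between -1.71 and -1.10. Immediate early genes had a median of -1.10 (camera adjusted p = 2.36e-04, adjusted p = 0.414 with an estimated correlation), and of -0.40 without non-responder replicate 1 (camera adjusted p = 0.0268). Of 20 p53 target genes 8 were lower (11 lower and 1 higher adjusted over the list alone), Mdm2 at -0.51, Zmat3 at -0.71 and Trp53inp1 at -0.65. The p53 target genes had a median of -0.58 (camera adjusted p = 4.55e-04, adjusted p = 0.414 with an estimated correlation). Of 23 MET signalling genes 3 were lower and 2 higher (10 and 3 adjusted over the list alone); Mmp12 and the phosphatase gene Dusp4 had -1.31 and -1.78, and Hgf, the ligand of MET, had 1.06. MET signalling genes had a median of -0.78 (camera adjusted p = 0.0111, adjusted p = 0.414 with an estimated correlation), and did not pass with the title number as a covariate (-0.329, camera adjusted p = 0.297). Nor did they pass with the log2 exon index as a covariate (-0.303, camera adjusted p = 0.448). Of 35 stellate cell and matrix genes 5 were lower and 1 higher (13 and 3 adjusted over the list alone), with Sparc at -2.01, Col4a2 at -0.78 and Ngfr at 1.37. Stellate cell and matrix genes had a median of -0.66 (camera adjusted p = 0.0364, adjusted p = 0.619 with an estimated correlation). Of 12 erythroid genes 4 were lower (5 adjusted over the list alone), the globin gene Hbb-bt at -1.22 and Slc4a1 at -2.05. Erythroid genes had a median of -0.81 (camera adjusted p = 0.0362, adjusted p = 0.437 with an estimated correlation). Of 36 ribosomal protein genes 0 passed in edgeR's test or adjusted over the list alone (11 at an unadjusted p under 0.05; 3 by DESeq2, 0 by limma-voom and 4 with quality weights), among them Rps4x, Rpl3 and Rplp0 at -0.40, -0.37 and -0.30. The ribosomal median was -0.28 (camera adjusted p = 2.76e-04, adjusted p = 0.559 with an estimated correlation). With the log2 index of Ctnnb1 and Met exon density as a covariate it turned to 0.198 and passed as higher in responders (camera adjusted p = 0.00297), and the stellate and immediate early medians turned to 0.220 and 0.205 without passing. The stellate list missed the threshold without responder replicates 1 and 6 and non-responder replicate 1 (camera adjusted p up to 0.652). With the 3′ coverage index as a covariate the stellate and ribosomal lists missed the threshold (medians -0.195 and -0.104, camera adjusted p = 0.561 and 0.0508). The erythroid list missed it without responder replicates 4 and 6 and non-responder replicates 1, 2 and 3 (up to 0.0808). So did the ribosomal list without non-responder replicate 1 (0.0502). All the called genes of this paragraph missed the threshold without non-responder replicate 2, with edgeR adjusted p from 0.05995 to 0.1229.

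Several lists of hepatocyte genes had higher medians in responders, some with few genes past the threshold or with genes past it both ways. Of 18 periportal hepatocyte genes 10 were higher and 8 did not pass (17 adjusted over the list alone), with a median log2 fold change of 1.36 (camera adjusted p = 1.07e-09, adjusted p = 0.414 with an estimated correlation). Of 31 urea cycle and amino acid genes 14 were higher and 17 did not pass (25 adjusted over the list alone). Urea cycle and amino acid genes had a median of 0.73 (camera adjusted p = 4.80e-11, adjusted p = 0.414 with an estimated correlation), and of 0.392 with the title number as a covariate (camera adjusted p = 2.1e-04). The urea cycle gene Ass1 had 1.55, the glutaminase gene Gls2 1.57, Uroc1 1.41, Gnmt 1.74 and the histidine ammonia lyase gene Hal 1.81. Of 30 oxidative phosphorylation genes 6 were higher (16 adjusted over the list alone), with Ndufb9, Uqcrc1 and Ndufb5 between 0.44 and 0.61. Oxidative phosphorylation genes had a median of 0.36 (camera adjusted p = 5.24e-09, adjusted p = 0.414 with an estimated correlation). Of 32 fatty acid oxidation genes 7 were higher (11 higher and 2 lower adjusted over the list alone), Acot1 at 1.79 and Acaa1b at 1.61. Fatty acid oxidation genes had a median of 0.35 (camera adjusted p = 6.48e-04, adjusted p = 0.437 with an estimated correlation). Of 43 drug and steroid metabolism genes 8 were higher and 3 lower (15 and 3 adjusted over the list alone), the sulfotransferase gene Sult1d1 at -1.14, Cyp2c39 at -0.94 and Gsta2 at 1.44. Drug and steroid metabolism genes had a median of 0.31 (camera adjusted p = 0.00359, adjusted p = 0.437 with an estimated correlation). Of 24 bile acid genes 6 were higher and 2 lower (10 and 3 adjusted over the list alone), with the exporter gene Abcc3 at 1.92 and Slc51b at -3.15. Bile acid genes had a median of 0.32 (camera adjusted p = 0.0111, adjusted p = 0.470 with an estimated correlation). With the exon density index as a covariate the bile acid and complement medians turned to -0.113 and -0.186 without passing (camera adjusted p = 0.768 and 0.118). The drug metabolism and gluconeogenesis lists did not pass then either (medians 0.106 and 0.104, camera adjusted p = 0.589 and 0.665). Periportal, urea cycle and fatty acid oxidation lists still passed, with medians of 0.390, 0.324 and 0.182. So did oxidative phosphorylation and circadian lists (0.286 and 0.309). Of 18 gluconeogenesis genes 3 were higher, Fbp1, Tat and Slc2a2 at 1.10 to 1.25 (4 higher and 1 lower adjusted over the list alone). Gluconeogenesis genes had a median of 0.34 (camera adjusted p = 0.0362, adjusted p = 0.437 with an estimated correlation). Of 23 complement genes 1 was higher, Mbl1 at 0.80, while C8g and C8b had 0.49 and 1.26 and did not pass (1 adjusted over the list alone). Complement genes had a median of 0.37 (camera adjusted p = 0.00523, adjusted p = 0.471 with an estimated correlation). Of 17 circadian clock genes 2 were higher, Nr1d1 at 0.81 and Nfil3 at 0.69, while Bhlhe41 had 1.72 and did not pass (3 higher and 1 lower adjusted over the list alone). Circadian clock genes had a median of 0.29 (camera adjusted p = 0.0306, adjusted p = 0.414 with an estimated correlation). The bile acid and complement lists missed the threshold without non-responder replicate 1 (camera adjusted p = 0.0862 and 0.102). With the 3′ coverage index as a covariate they missed the threshold too (camera adjusted p = 0.0892 and 0.131). The gluconeogenesis list missed it without responder replicates 5 and 6 and non-responder replicates 1, 2 and 4 (up to 0.108). With the title number or the 3′ coverage index as a covariate the gluconeogenesis list did not pass either (0.0679 and 0.0771). The circadian list missed it without responder replicate 6 and non-responder replicates 2 and 4 (up to 0.0729). Cyp2e1 had 0.44 ± 0.32 (SE) and Alb -0.60 ± 0.18 (SE), and neither passed (edgeR adjusted p = 0.402 and 0.0524). Without non-responder replicate 2, Acot1, Sult1d1, Abcc3 and Nr1d1 kept an adjusted p of at most 0.0492 and the other called genes of this paragraph did not, with adjusted p from 0.0544 to 0.128.

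Lists of sex-biased liver genes differed too. Of 18 female-biased genes 6 were lower and 1 higher in responders (9 and 1 adjusted over the list alone), A1bg, Cyp2a4 and Cyp17a1 at -6.79, -2.45 and -4.56. Female-biased genes had a median of -2.06 (camera adjusted p = 6.73e-04, adjusted p = 0.414 with an estimated correlation), and of -0.351 with the title number as a covariate (camera adjusted p = 0.0431). With the exon density index as a covariate their median was -1.03 and the list did not pass (camera adjusted p = 0.066). Of 19 male-biased genes 1 was higher, Susd4 at 2.98, while Serpina1e and Cyp2u1 had -0.51 and 2.33 and did not pass (2 higher and 1 lower adjusted over the list alone). Male-biased genes had a median of 1.27 (camera adjusted p = 4.91e-05, adjusted p = 0.437 with an estimated correlation), and of -0.0556 with the exon density index as a covariate (camera adjusted p = 0.718). A1bg kept the threshold without non-responder replicate 2 (edgeR adjusted p = 0.0275), and Cyp2a4, Cyp17a1 and Susd4 did not (0.0568, 0.0621 and 0.0743). Lists that did not pass in camera were acute phase (adjusted p = 0.0676), glycolysis and hypoxia (0.0721), endothelial (0.104), Wnt components (0.122), X-inactivation and Y-linked (0.133), heat shock (0.243), fatty acid synthesis (0.272), cholesterol synthesis (0.349), B and plasma cell (0.517), cholangiocyte (0.517), unfolded protein response (0.535), NRF2 (0.586), hepatocyte secreted (0.689), adipocyte (0.850), TGF-beta response (0.901) and macrophage (0.946). Muscle and pancreas lists had 2 and 4 measured members and were not tested. In all, 28 of 44 lists passed with the preset correlation, 10 higher and 18 lower, and with an estimated one 0 did by camera (0 at an unadjusted p under 0.05, smallest 0.0518). Fry tests whether a list's genes move one way on balance. By it 12 lists passed (23 at an unadjusted p under 0.05). Among them were 10 of the 28, glycolysis and hypoxia (adjusted p = 0.0318) and Wnt components (0.00669). Median and test differed in sign for the unfolded protein response list (median 0.12, mean -0.36, test down) and the TGF-beta list (median -0.15, mean -0.36, test up). Mean and test did so for the macrophage list (mean -0.02, test up).

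**Figure D2:**
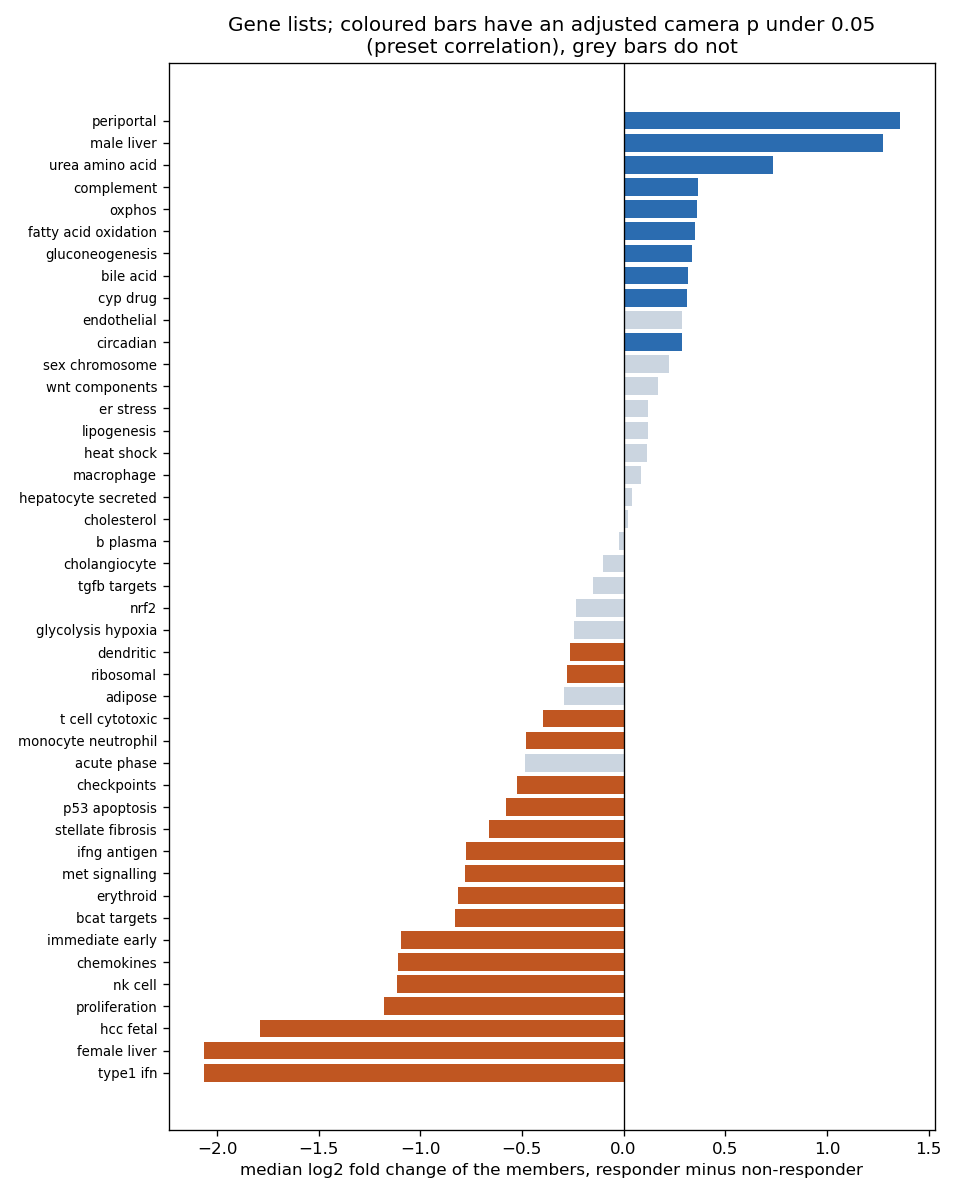
Median log2 fold change, responder minus non-responder, of each gene list with 5 or more measured members; bars are medians over members, coloured where the camera adjusted p with a preset correlation passed. The type I interferon list lies lowest with -2.07 and the periportal list highest with 1.36.

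The tumours were induced with MET and β-catenin, so the reads over the exons of the mouse genes were compared. Ctnnb1 (ENSMUSG00000006932, mm10 chromosome 9, from 120929216), which encodes β-catenin, stood at 332 ± 38.7 CPM (SD, n = 6) in responders and 505 ± 133 (SD, n = 4) in non-responders, a log2 fold change of -0.60 ± 0.17 (SE, edgeR adjusted p = 0.0476) that kept the threshold in 2 of 10 fits with a library left out, those without responder replicate 4 and non-responder replicate 1 (adjusted p up to 0.1555 in the others). Met (ENSMUSG00000009376, chromosome 6, 17463800 to 17573980) had 99.6 ± 8.75 and 93.4 ± 33.3 CPM and a log2 fold change of 0.09 ± 0.22 (SE, edgeR adjusted p = 0.823). Exon 12 of Ctnnb1 (chromosome 9, 120957517 to 120957667), counted in genome order, held 6.08% ± 1.99 (SD, n = 6) of the gene's exon reads in responders and 11.998% ± 3.67 (SD, n = 4) in non-responders (two-sided exact permutation p = 0.0190, adjusted p = 0.0542), and 5.03% in the untreated library. Exon 17 of Met (chromosome 6, 17555547 to 17555627) held 2.65% ± 1.17 (SD, n = 6) and 6.09% ± 2.14 (SD, n = 4) (two-sided exact permutation p = 0.0286, adjusted p = 0.0587), and 1.91% in the untreated library. Both exons were singled out after their values were seen. Of 37 exons tested 0 passed by the exact permutation test, whose smallest adjusted p was 0.0542. Its smallest unadjusted p, 0.00952, is the lowest that this test can give for 6 against 4 libraries. No exon could therefore pass on its own after adjustment over 37, so the 0 does not show that the shares were alike. In all, 25 had an unadjusted p under 0.05, 7 with a lower and 18 with a higher share in responders. Shares within a gene add up to its whole, so a gain in some exons lowers the others, and these counts are not of separate results. Without responder replicate 6, 18 exons passed. A log2 index of the density over both exons was 1.03 and 1.41 in responder replicates 4 and 6 and 0.13 to 0.37 in the other responders, and 3.53, 2.34, 1.31 and 1.47 in non-responder replicates 1 to 4. With that index as a covariate, 1 gene was called by edgeR between responders and non-responders (2426 at an unadjusted p under 0.05), and the median change of the 1748 genes was 0.5073 (median SE 0.265).

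**Figure D3:**
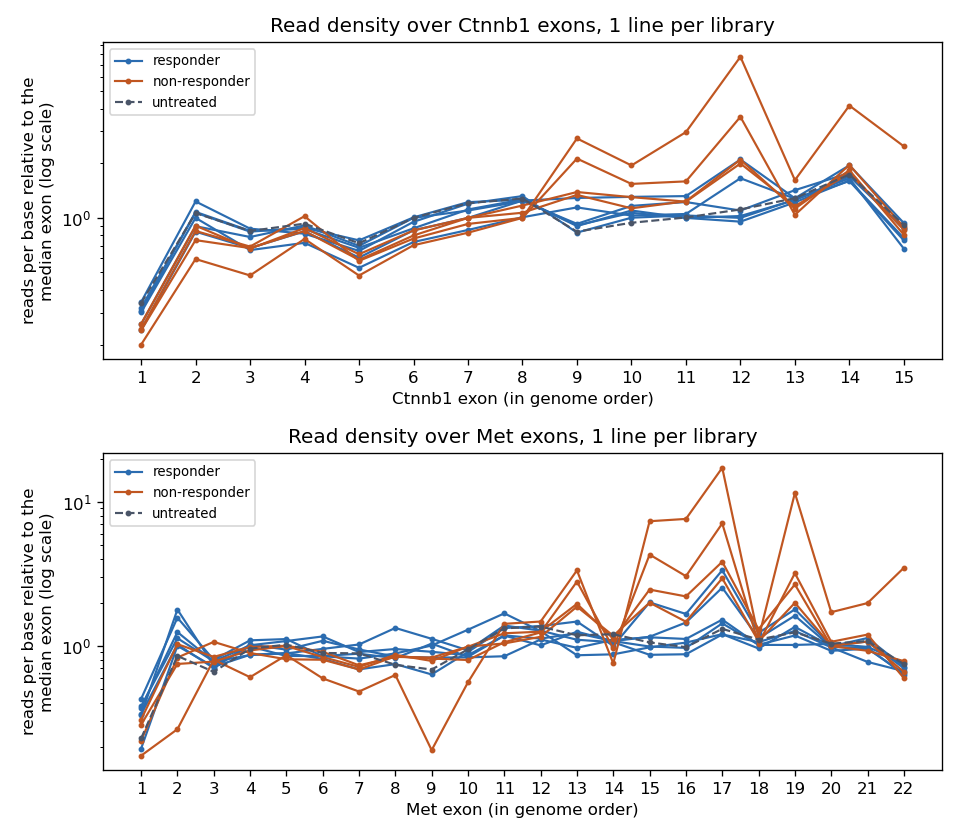
Reads per base over each Ctnnb1 and Met exon relative to the median exon of the same library (log scale), with 1 line per library. Ctnnb1 exon 12 was at 7.73, 3.61, 2.10 and 1.99 in non-responder replicates 1 to 4 and at 0.953 to 2.10 in responders, and Met exon 17 was at 17.3, 7.09, 2.95 and 3.84 against 1.20 to 3.35.

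The single untreated library was set beside the treated groups without a test. Over 9236 genes with an average log2 CPM of 3 or more, it lay above the range of the 10 treated libraries for 11.81% and below it for 6.691%. Each treated library, set against the other 10 the same way, lay above for 3.627% to 23.14% and below for 1.722% to 40.3%, the highest in non-responder replicate 1. The untreated library's Spearman correlation across genes, which are not independent replicates, was 0.948 to 0.983 with responders and 0.769 to 0.926 with non-responders. Its Afp stood at 1.66 CPM, scaled to library size only, and its log2 exon index at 0.274. Responder replicates 1, 2, 3 and 5 had Afp at 1.39 to 2.28 CPM and an index of 0.13 to 0.37. Every non-responder had Afp at 116.7 CPM or more. How much tumour the untreated library held was not tested. Farthest above the range were Asic2, Rad54l2, the pro-apoptotic gene Bmf (35.1 CPM against at most 19.9), the glucose-6-phosphatase gene G6pc (490.8 against at most 287.3) and Tppp (81.5 against at most 48.0). Asic2 had 161.2 CPM there and 0 in every treated library, and Rad54l2 had 229.6 against at most 50.5, in each gene with most reads over a single exon. Farthest below were Akr1b7 and Kif5c, both at 0 CPM, Ipcef1 at 0.311, Tubb2a at 8.67 and Sult3a1 at 0.0415, where the lowest treated values were 0.101, 0.0545, 0.681, 15.9 and 0.120. The median of 17 type I interferon genes lay at -0.54 (log2) against the responder mean and at -1.36 against the non-responder mean, each at percentile 0 of 10000 random lists matched on expression. For 17 periportal genes the medians were 0.25 and 1.65 (percentiles 99.99 and 100), for 11 fetal liver genes -1.51 and -6.97 (both percentile 0) and for 24 β-catenin target genes -0.70 and -1.50 (both percentile 0). Such percentiles were common for this library: of 36 lists 18 lay under percentile 2.5 or over 97.5 against responders and 27 against non-responders. In 4 lists the medians differed in sign, among them immediate early genes (0.29 against responders, percentile 99.99, and -0.38 against non-responders, percentile 0.58) and stellate genes (0.06, percentile 77.3, and -0.57, percentile 0).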

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

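The tests of degraded RNA, of trends within the responders, of the exon index as a covariate, of 3′ coverage bias and of injected-gene transcripts were chosen only after the results were seen. The bound for the splits of the libraries was written before the splits were run but after the counts of genes and lists were seen. Of 250 groups of 4 or 6 libraries tested for a library standing apart, 16 had one, where chance gives about 1 in 20.

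The 3′ coverage index was 1.19 in non-responder replicate 1 against -0.12 to -0.06 in the others of its group, and 0.0681 in responder replicate 6 against -0.197 to -0.112 in the others of its group. On the log2(CPM + 1) scale, non-responder replicate 1 also stood apart for Met (5.50), Mki67 (4.18), Emr1 (0.972), Bst2 (7.96) and Bex1 (1.51). Responder replicate 6 stood apart for Klrb1b (1.52), Pdcd1 (0.320) and Bex1 (0.232), and responder replicate 1 for Cyp2c39 (5.74), Slc4a1 (0.647) and Mmp12 (1.25). Single values were Ccl4 in non-responder replicate 3 (0.693), Klrb1c in non-responder replicate 2 (3.12) and Pnliprp1 in responder replicate 4 (0.343).

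In the untreated library 7777 reads lay over exon 4 of Asic2 (chromosome 11, 80893974 to 80894124, 151 bases) and 0 over its other exons, with 0 over that exon in the treated libraries. Exon 1 of Rad54l2 (chromosome 9, 106788980 to 106789194) held 9235 reads there against 18 to 44 in the treated libraries, while its other exons held 1997 reads against 934 to 2011.

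The first pattern is the 1748 genes that differ between responders and non-responders. Chance in how the libraries were grouped is argued against for both directions, though 100 drawn splits of 210 possible ones cannot exclude it. Of these 100 splits of the 10 libraries, 1, the real one, gave as many higher genes (723, highest other 1). Likewise 1, again the real one, gave as many lower genes (1025, highest other 3). Degraded RNA in non-responder replicate 1 is argued against as the whole source, since 1153 of the genes were called again without it. Tumour content, if the exon index reads it, stays open as a source of part of the difference. Within the 6 responders 87.81% of the called genes followed the index in the direction of the group difference. The median over all orders of the index was 51.89% (one-sided exact permutation p = 0.0222). The 3′ coverage index ranks the responders almost alike, highest in replicates 6 and 4 (0.0681 and -0.112) and lowest in replicate 5 (-0.1968). This test therefore cannot tell tumour content from 3′ coverage. With the index as a covariate the median log2 change of the called genes went from 1.01 (SE 0.23) to 0.51 (SE 0.27), and 1 gene was still called, since the change shrank as its SE grew. The index itself differed between the groups (two-sided exact permutation p = 0.0190), and its exons were singled out after their values were seen. As a covariate it therefore takes up part of any group difference. Its highest value (3.53) is that of non-responder replicate 1, whose 3′ coverage index was 1.19, so the shrinkage does not single out tumour content. With the 3′ coverage index as a covariate instead, 1467 genes were called, 1046 of them among the 1748. These values argue against 3′ coverage as the whole source of the difference. A trend with the number in the sample title stays open, with 84.95% of called genes following it against a median of 47.45% (one-sided exact permutation p = 0.0833), since the numbers nearly separate the groups. With the number as a covariate the median log2 change of the called genes was 0.846 (SE 0.3666) and 1748 of 1748 kept their sign, 948 at an unadjusted p under 0.05, so the calls ended mainly because the SE grew. Response itself, which the labels name, is untested apart from both.

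The second pattern is the 28 gene lists past the threshold, which 2 of 100 splits matched. That share lay under the bound set for the splits, but it does not exclude chance. The highest other split gave 29 lists, more than the real one, and the median other split 14. Camera with a preset correlation thus called many lists in other groupings too, and 100 of 210 possible splits were drawn. Other splits can keep part of the response label: the one with 29 lists has all 4 non-responders on one side.

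The third pattern is the uneven density over Ctnnb1 and Met exons in non-responders. A 3′ coverage bias would raise the last exon of each gene at least as much as the exons before it. In non-responder replicates 2 to 4 together, over both genes, the exons in the later part of the transcript, without the last, were denser than the last exon by 0.40 more (log2) than in responders (two-sided exact permutation p = 0.0476). In replicate 2, at 1.35 against 0.478 to 0.932 in responders, such a bias is argued against as the whole source. Replicates 3 and 4, at 0.959 and 0.903, lay beside responder replicates 4 and 6 (0.932 and 0.868), so the test does not decide for them. In non-responder replicate 1 a 3′ coverage bias stays open. There the ratio of the later exons to the last exon differed from the responder mean by -0.67 (log2), as such a bias predicts. The coding part of the last Ctnnb1 exon, however, was denser than its UTR part by 1.807 against at most 1.135 in responders. Over all 10 libraries the ratio differed by 0.128 (two-sided exact permutation p = 0.657). Transcripts of the injected genes, which would lack the mouse 3′ UTR, are a candidate source: the coding part of the last Ctnnb1 exon was denser than its UTR part by 0.74 more (log2) in non-responders than in responders (two-sided exact permutation p = 0.0381). Non-responder replicates 1 and 2 (1.807 and 1.63) lay above every responder. Replicates 3 and 4 (1.073 and 0.93) lay within the responder range of 0.318 to 1.135. The labels do not give the sequence of the injected genes, and it was not analysed here.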

How the results depend on the processing

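The log2 exon index and the 3′ coverage index were covariates chosen after seeing the data; the others were set before. No gene called in the report changed sign with another scaling, filter, test or left-out library; with the exon index as a covariate 27 of the 1748 did. Higher and lower counts stayed within 1.5 times with RLE, upper quartile or library size scaling, both other filters, limma-voom, exon sums, the untreated library in the model and the 3′ index. They were 1349 and 1696 by DESeq2, 1611 and 2012 by limma-voom with quality weights, 1372 and 1808 at an adjusted p under 0.1, 11 and 18 by glmTreat against 0.5, 0 and 1 with the title number as a covariate (1857 genes at unadjusted p under 0.05), and 0 and 1 with the exon index (2426). The median change of the 1748 genes, 1.009 without a covariate, was 0.846 with the title number (0 signs turned, SE from 0.2307 to 0.3666) and 0.5073 with the exon index (SE 0.265). Higher genes were 1456 with 1 surrogate variable. Leaving out 1 library gave 38 to 836 higher and 41 to 1158 lower genes, lowest without non-responder replicate 2. Fits with fewer libraries or more covariates have fewer residual degrees of freedom. Leaving out any 1 library costs the same number of them, so they cannot account for the spread between those fits. That spread ran from 79 genes called without non-responder replicate 2 to 1994 without non-responder replicate 3, and its cause was not tested. The 28 lists became 0 with a correlation estimated from these data (smallest camera adjusted p = 0.414), 12 by fry, and 20 to 30 with 1 library left out. With the title number 26 lists passed, 4 of them new, and the lists lost were β-catenin targets (median -0.26, from -0.83), MET signalling (-0.33), natural killer (-0.998), T cell (-0.29), dendritic (-0.26) and gluconeogenesis (0.27); of 28 medians 8 shrank by more than 1.5 times, among them female-biased (-0.351), fetal liver (-0.711) and proliferation (-0.568), and 2 grew as much. With the exon index 21 passed (9 lost, 2 new, ribosomal in the other direction). Lost were bile acid, complement, drug metabolism, female-biased (-1.03), male-biased, gluconeogenesis, immediate early, MET signalling and stellate. Of the medians 10 shrank by more than 1.5 times, among them periportal (to 0.390), fetal liver (-0.653), type I interferon (-0.928) and urea cycle (0.324), and 3 grew as much. With the 3′ index 22 passed (7 lost, 1 new). Lost were bile acid, complement, dendritic, gluconeogenesis, monocyte and neutrophil, ribosomal (-0.104) and stellate (-0.195). In that fit 5 medians shrank as much. Without non-responder replicate 1, 6 did: immediate early (-0.40), stellate (-0.20), ribosomal (-0.11), bile acid (0.13), complement (0.198) and monocyte (-0.270). So did T cell (-0.13) without non-responder replicate 3, dendritic (-0.156) without responder replicate 1 and erythroid (-0.529) without non-responder replicate 2, while 3 grew as much without responder replicate 3. Exons past the threshold were 0 to 18 with 1 library left out, 18 without responder replicate 6. In the untreated library 8.203% and 7.987% of genes lay above and below the treated range with library size only, and 14.55% and 5.477% at an average log2 CPM of 5.

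With the exon index as a covariate the lists bile acid (-0.11), complement (-0.19), male liver (-0.056), ribosomal (0.20, past the threshold as higher), stellate (0.22) and immediate early (0.20) turned, as did Met (-0.51), Cyp2e1 (-0.18), Emr1 (-1.94) and S100a8 (-0.30), genes not called. Other uncalled genes turned as follows: Met with quality weights (-0.034), 1 surrogate variable (-0.0099) and the 3′ index (-0.15); Emr1 with the same settings (-0.19, -0.021 and -0.42); with the title number Afp (0.76), Cd3e (0.39), Emr1 (-0.62) and S100a8 (-1.01); and S100a8 with library size only (-0.0082) and exon sums (-0.048). With 1 library left out the H2-Ab1 log2 fold change ranged from -0.63 to 0.14, and that of the others from -0.14 to 0.24 for Met, -0.45 to 0.13 for Cd3e, -0.27 to 0.31 for Emr1 and -0.30 to 0.28 for S100a8. The cause was not tested. Sex class could not be a covariate, since the libraries did not fall into both classes. Of 101 called genes that the naming rule took 16 passed in every leave-one-out fit and 85 missed it without non-responder replicate 2. In simulated data at this depth and size 6.25% of the 1.5-fold changes that passed the filter were found, so small changes are mostly beyond reach.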

Other observations

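Genes outside the lists past the threshold also differed. The endothelial gene Lyve1 had a log2 fold change of -1.44 and the tetraspanin gene Cd9 one of -1.16 in responders, and the serum protein gene Ahsg had -1.04. The Wnt receptor gene Fzd5 had 0.78 and the kinase gene Pdk1 0.99. Me1, the malic enzyme gene, rose from 85.8 ± 23.3 CPM (SD, n = 4) in non-responders to 212 ± 41.8 (SD, n = 6). The stress gene Trib3 had -1.85, the receptor gene Tgfbr2 -1.15 and the adipocyte gene Fabp4 -1.45. Pnliprp1, a pancreatic lipase relative, had 0.0531 CPM in responders and 0.575 in non-responders. Of these, Cd9 passed in every fit with 1 library left out, and the others missed the threshold without non-responder replicate 2, with adjusted p from 0.0512 to 0.132.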
